A study of Mus musculus with 7 samples.

How the data were processed

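Transcripts were measured by Xenium in situ on 7 fresh-frozen coronal hemisections of wild-type mouse brain, each 10 µm thick, per the labels' protocols. The authors' deposited count table holds whole-number transcript counts per gene and segmented cell, and its cell sums equalled the deposited per-cell totals in 100% of cells. Seurat is named in the submitters' processing notes, and its version is not given in the sources used here. Segmentation, transcript decoding and any filter on cells are not given in the sources used here. The deposited table of cells names the section of each cell and lists counts of control probes and codewords per cell, which served as the background. It also holds totals after Seurat's SCT transformation, a normalised score whose settings are not given per the file headers, and these were not used. The count table and the cell table list the same barcodes in another order, so they were joined by barcode. Of 297 gene symbols, 296 matched the mouse RefSeq gene table, and 2010300C02Rik did not. Neither a cell annotation nor cell positions were used here.

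Sections were grouped by position and replicate number as the labels give them. The labels do not say that a shared replicate number marks a shared animal, and none was assumed. Cells with at least 10 transcripts (382707 of 384076) were clustered. Each count was divided at random into 2 parts (binomial, 50%), and cells were clustered on the first part after scaling to the median depth, log transformation, 30 principal components, a graph of 15 neighbours and the Leiden method (resolution 1.0, scanpy 1.11.5 with igraph 0.11.9, fixed seed). Levels and main tests used the second, held-out part unless stated, and some alternatives used the first part or all counts. Both parts of a cell share its true composition, so dividing the counts removes the reuse of counting noise and not the variation between cells by which the clusters were drawn. No doublet caller was run, because segmented cells in tissue are not droplets, and a segmented cell can hold transcripts of its neighbours. Clusters were named only where 3 of their 10 leading genes (of those with at least 0.2 transcripts per cell) belonged to 1 of 19 cell type marker lists. Candidate thalamic clusters had Slc17a6 at least 2-fold above and Gad1 and Gad2 at least 8-fold below all other cells. This rule was set after the clusters were seen. Candidate cells were clustered again (resolution 0.6), and sub-clusters with 2 or more markers of a glial or vascular list among their 10 leading genes were set aside. Clusters with at least 10 cells in every section were compared. Some measured genes are not reported here, while the counts of genes include them.

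For each pair of clusters, held-out counts were summed per replicate number and cluster and tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): genes kept by filterByExpr, TMM scaling, the quasi-likelihood F test with the replicate number as a block (9 residual degrees of freedom) and Benjamini-Hochberg adjustment over the genes tested at 0.05. Sums of replicate 1 join 3 positions, those of replicate 2 join 2, and replicates 3 and 4 are posterior sections, so position and replicate number overlap in these sums. Position was tested on sums per section with edgeR and no block. The SE given with a log2 difference is its absolute value divided by the square root of the quasi-likelihood F statistic. The interaction of cluster and position had the section as a block. A comparison of anterior with other thalamic neurons was planned and not run, because the markers did not separate these classes, and the planned interaction with that class was replaced by the interaction with cluster. Shares of clusters were compared by a two-sided exact permutation test (scipy 1.17.1), and 95% intervals of shares are Wilson intervals. Where no cell was found, the limit given is 3 cells of the total. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

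The design, the tests, the marker lists, 9 gene groups and the rule for named genes were fixed before the data were examined. The neuropeptide and receptor group also held Igf1, Bdnf and the cerebellin genes Cbln1 and Cbln4, which are neither neuropeptides nor their receptors. For each pair the rule takes, among genes past the threshold that moved one way in all 4 replicates, the 10 with the largest log2 difference in each direction, plus up to 4 genes of each group past the threshold. Of the genes it took, those named in the text are examples. Alternatives were DESeq2 1.42.0, library size in place of TMM, no low-count filter, cells with at least 50 transcripts, leaving out glial and vascular genes, sections as units, leaving out the block, adding a replicate block or slide term, clusters rebuilt on the other part of the counts, and leaving out each replicate or section in turn. Clustering on all counts, clustering on genes other than those tested (148 and 149 genes in turn), and sums over the 4 compared clusters alone were added after the data were seen. So was, for position, the use of clusters rebuilt on the other part of the counts. In the tested-without check a gene counts only where it passed in the same direction. Its clusters were matched to the main ones by the label most of their cells held, and it used all counts.

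The tests were checked on simulated counts drawn from the means and library sizes of the real sums, with 60 genes changed by known folds, 20 at each fold. For the Myo5c and Pamr1 clusters (192 genes) 20% of genes changed 1.5-fold, 70% changed 2-fold and 90% changed 4-fold were recovered, and 0 of 132 unchanged genes were called by edgeR. For position over all neurons (283 genes) these were 0%, 5% and 55%, with 1 of 223 unchanged genes called. Within the C1ql2 cluster (163 genes) they were 15%, 60% and 100%, with 2 of 103 unchanged genes called. They were 0%, 20% and 75% within the Myo5c cluster (0 of 140 called by edgeR), 0%, 45% and 75% within the Pamr1 cluster (1 of 146), 5%, 0% and 55% within the Htr2c cluster (1 of 143), and for the interaction (203 genes) 5%, 5% and 45%, with 0 of 143 called. Dividing the counts was tested on 4000 simulated cells of a single kind, parted at the median of their first principal component: groups formed on one part of the counts gave 0 of 268 genes when tested on the other part, against 61 of 290 when grouped and tested on all counts.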

Results

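The data are in situ transcript counts from coronal hemisections of wild-type mouse brain that pass through the anterior thalamic nuclei, a group of relay nuclei of the limbic system. They were measured with Xenium, an imaging method that decodes single transcripts of a fixed gene panel in tissue and assigns them to segmented cells. The 7 fresh-frozen sections, each 10 µm thick, were taken at an anterior position (bregma -0.58 mm, 2 sections), an intermediate position (bregma -0.70 to -0.82 mm, 2 sections) and a posterior position (bregma -0.94 mm, 3 sections). Replicates 1 and 2 lay on one slide and replicates 3 and 4 on another, so that slide held posterior sections only. The table covered 297 genes and 384076 cells with 146504697 transcripts, and the median cell held 339. Totals per section ran from 17438577 transcripts in 53315 cells (anterior replicate 1, median 278 per cell) to 23432215 in 55603 cells (intermediate replicate 2, median 383). The median was 364 in anterior replicate 2, 302 in intermediate replicate 1, 345 in posterior replicate 1, 305 in posterior replicate 3 and 390 in posterior replicate 4. Control probes, which match no transcript, gave between 0.379 counts per cell (anterior replicate 2) and 0.870 (posterior replicate 3). The labels do not say whether replicates came from separate animals, so every p-value measures the spread between these sections, which may be technical.

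The study examined the transcriptomes of anterior thalamic neurons, and the first question was which neuron groups the sections held. No cell annotation or cell position was used, so cells were grouped by their counts. Of 36 clusters, 4 with 18172 cells had high Slc17a6, which encodes the vesicular glutamate transporter VGLUT2 used by thalamic relay neurons, and low Gad1 and Gad2, which encode the GABA-synthesising enzymes. They split into 13 sub-clusters, and 6 of these, with 8580 cells, carried glial or vascular markers among their leading genes and were set aside. The set-aside share ran from 34.5% of candidate cells in posterior replicate 3 to 53.8% in posterior replicate 4. The remaining 7 sub-clusters held 9592 neurons, 2.50% of all cells. A name took 3 markers of a list among the 10 leading genes, and the panel measured 1 anterodorsal, 2 anteroventral and 3 anteromedial markers, so the panel alone ruled out a name for the anterodorsal and anteroventral nuclei. No cluster met the rule for the anteromedial nucleus, and each is called here by a leading gene. The Myo5c cluster held 2749 cells, the Pamr1 cluster 2235, the Htr2c cluster 1778 and the C1ql2 cluster 1161. The Tacr1, Pvalb and Tmem132d clusters held 744, 718 and 207 cells, were nearly missing from some sections and entered no pairwise test. C1ql2 is known as a marker of the anterodorsal nucleus. The Htr2c cluster had Calb2 and Nts among its 10 leading genes, the 2 measured markers of the paraventricular and midline thalamus list, so it may lie outside the anterior nuclei. Whether these clusters correspond to nuclei was not tested.

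The 4 larger clusters were compared in pairs to find which genes set them apart. Clusters were formed on a random part of each cell's transcripts (50% in expectation), and levels and main tests come from the other, held-out part. Sums were made per replicate number and cluster (n = 4 sums per cluster), so replicates 3 and 4 stand for posterior sections only. Of 262 genes tested with edgeR's quasi-likelihood test, 217 passed a Benjamini-Hochberg adjusted p of 0.05 in at least 1 of the 6 pairs, and 10 passed in every pair. These 10 were Arhgef28, Calb2, Cpne6, Epha1, Epha8, Foxp1, Foxp2, Myo5c, Nectin3 and Nrp2. Because clusters are defined by expression, a gene that helped to form a cluster is not independent evidence of its difference. Each gene was therefore also tested between clusters formed on a set of genes that left it out. Those clusters took the main label that most of their cells held, were drawn within the same candidate cells and were tested on all counts. That check is thus not fully independent of the tested gene. Replicate 3 consisted of 1 section with 45 Pamr1-cluster and 17 C1ql2-cluster cells, and its sums were the shallowest for the Myo5c, Pamr1 and C1ql2 clusters. Slc17a6 was high in all 4 clusters, at 12.2 ± 1.28 held-out transcripts per cell in the Myo5c cluster (SD, n = 4), 11.9 ± 2.84 in the Pamr1 cluster, 11.6 ± 2.67 in the C1ql2 cluster and 9.58 ± 0.655 in the Htr2c cluster. Control probes gave 0.596 counts per neuron, which is at most 0.0496 held-out counts per probe, since up to 6 different probes were seen in 1 cell. In 27 of 84 combinations of a gene and a pair that were checked, not all of them named below, the lower level lay at or under that bound, so the size of those folds is not exact. Among these are the folds of C1ql2, Bhlhe22, Pdyn, Spp1, Cbln4 and Rab3b, of Slit2 against the Myo5c and Pamr1 clusters, and of Calb1, Ramp3 and Htr2c against the C1ql2 cluster. Necab1 averaged 0.0557 in the Myo5c cluster, just over that bound, with 0.131 in posterior replicate 4 and 0.0238 in posterior replicate 1. Its folds against the Myo5c cluster are thus not exact either.

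**Figure D1:**
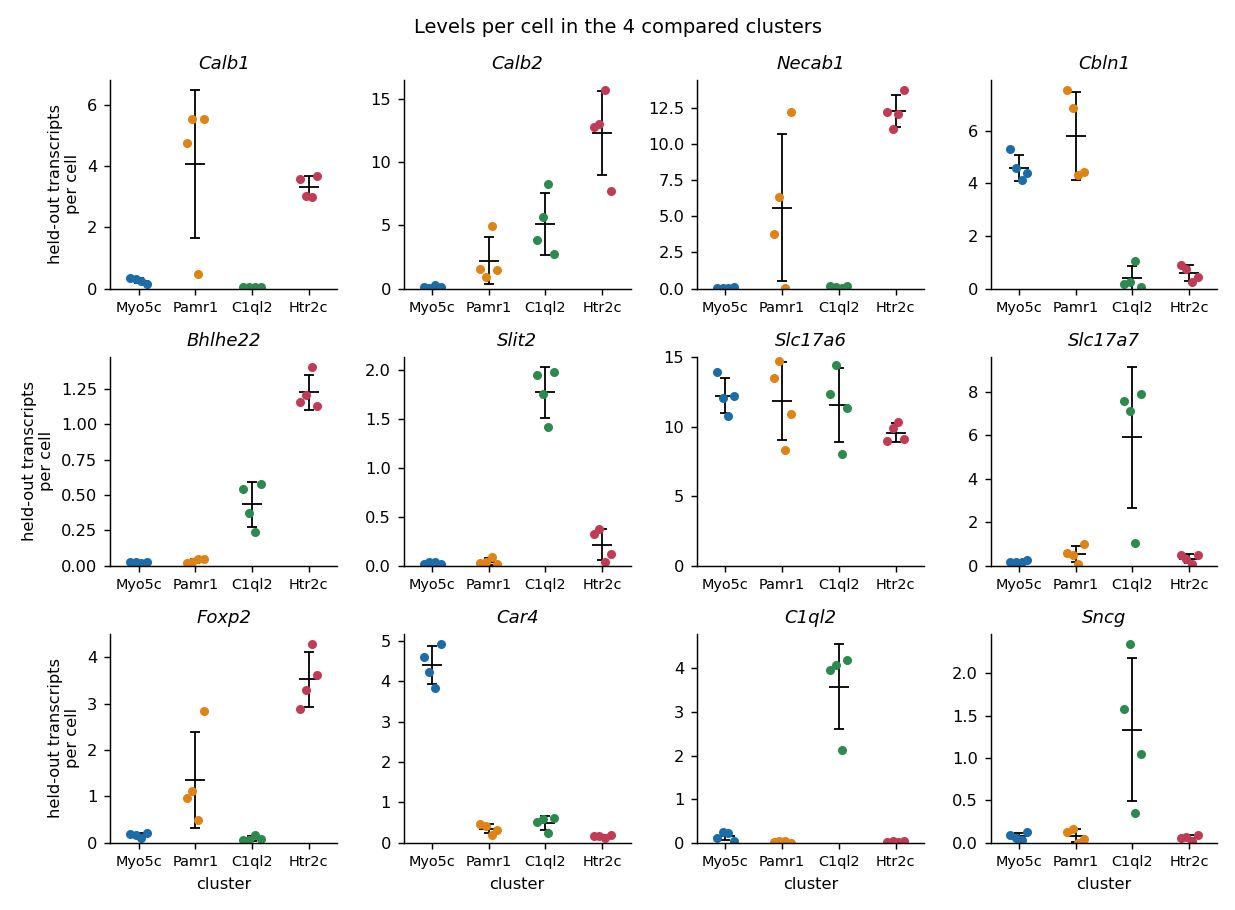
Held-out transcripts per cell (linear vertical axes from 0) of 12 genes in the Myo5c, Pamr1, C1ql2 and Htr2c clusters (horizontal axis). Points are the 4 replicate sums divided by cells, horizontal ticks their means and bars 1 SD; Slit2 averaged 1.77 in the C1ql2 cluster and 0.0273 in the Myo5c cluster.

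The Myo5c and Pamr1 clusters differed in calcium-binding proteins, Ramp3 and Car4. Necab1, a neuronal calcium-binding protein, was 86.6-fold higher in the Pamr1 cluster, at 5.61 ± 5.11 held-out transcripts per cell (SD, n = 4) against 0.0557 ± 0.0501. Calb1, which encodes calbindin, and Calb2, which encodes calretinin, were 13.0-fold and 12.7-fold higher in the Pamr1 cluster. Ramp3, a receptor-activity-modifying protein, was 28.7-fold higher there, with a level of 0.0608 ± 0.0115 in the Myo5c cluster and 2.08 ± 1.33 in the Pamr1 cluster. Car4, a carbonic anhydrase, was 13.5-fold higher in the Myo5c cluster (log2 difference 3.75 ± 0.22, SE, edgeR adjusted p = 3.77e-08), and the guidance receptor Nrp2 was 4.61-fold higher there. In all, 34 genes were higher in the Myo5c cluster and 50 in the Pamr1 cluster, and 78 of the 84 also passed in the same direction with clusters formed without them. By group, 1 of 7 tested calcium-binding proteins was higher in the Myo5c cluster and 4 were higher in the Pamr1 cluster (5 adjusted over the list alone). Of 19 axon guidance and adhesion genes, 4 were higher in the Myo5c cluster and 3 in the Pamr1 cluster (7 adjusted over the list alone). Of 19 transcription factors, 1 and 5 were higher in the Myo5c and Pamr1 clusters (7 adjusted over the list alone), with Tox 8.03-fold and Foxp2 6.92-fold higher in the Pamr1 cluster. All 4 of 10 tested release-machinery genes that passed were higher in the Pamr1 cluster, among them Unc13c at 4.58-fold (4 adjusted over the list alone). The 3 of 8 neuropeptide and receptor genes that passed were also higher there, with the opioid precursor gene Pdyn at 7.49-fold (3 adjusted over the list alone). As fixed, that list also holds Igf1, Bdnf, Cbln1 and Cbln4, which are of other kinds. Of 12 channel and receptor genes, 2 and 1 were higher in the Myo5c and Pamr1 clusters (3 adjusted over the list alone), and of 8 matrix genes 1 and 1 were (3 adjusted over the list alone). No activity-regulated gene of 5 and no transmitter gene of 4 passed with edgeR, over all genes or adjusted over the list alone. Of 47 glial, vascular and meningeal markers, 3 passed (2 adjusted over the list alone). The count of genes was 57 without replicate 2 and 131 without replicate 3.

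The C1ql2 cluster stood apart from the Myo5c cluster by an axon guidance ligand and by a vesicular glutamate transporter. Slit2, which encodes the guidance ligand, was 59.6-fold higher in the C1ql2 cluster, at 1.77 ± 0.260 held-out transcripts per cell against 0.0273 ± 0.0126 (SD, n = 4, edgeR adjusted p = 3.16e-06), Calb2 29.0-fold and Cabp7 11.8-fold. Slc17a7, which encodes the transporter VGLUT1, was 20.8-fold higher, at 5.90 ± 3.25 against 0.194 ± 0.0314, with a log2 difference of -4.38 ± 0.49 (SE) that moved to -5.03 without replicate 3. Sema3e, a semaphorin, was 13.2-fold higher in the Myo5c cluster, Calb1 8.43-fold and Rims3 3.65-fold. Here 69 genes were higher in the Myo5c cluster and 75 in the C1ql2 cluster, and 120 of the 144 also passed in the same direction with clusters formed without them. Axon guidance and adhesion genes split 5 and 8 between the Myo5c and C1ql2 clusters among 19 tested (14 adjusted over the list alone). Transcription factors split 6 and 3 among 19 (9 adjusted over the list alone), with Bhlhe22 15.9-fold higher in the C1ql2 cluster. Release-machinery genes split 1 and 5 among 10 (6 adjusted over the list alone), with Sncg 14.0-fold higher in the C1ql2 cluster. Channel and receptor genes split 3 and 4 among 12 (7 adjusted over the list alone), calcium-binding proteins 1 and 2 among 7 (3), and neuropeptide and receptor genes 2 and 3 among 8 (5). Activity-regulated genes split 1 and 2 among 5 (3 adjusted over the list alone). Bdnf was 2.65-fold and Arc 2.30-fold higher in the C1ql2 cluster, and Arc no longer passed edgeR's test without replicate 1 (adjusted p = 0.0683) or with clusters rebuilt on the other part of the counts (adjusted p = 0.129). Of 4 transmitter genes only Slc17a7 passed (1 adjusted over the list alone), and matrix genes split 1 and 1 among 8 (2). Of 47 glial, vascular and meningeal markers, 6 were higher in the Myo5c cluster and 8 in the C1ql2 cluster (11 adjusted over the list alone).

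The Myo5c and Htr2c clusters also differed in calcium-binding proteins. Necab1 was 272-fold higher in the Htr2c cluster, at 12.3 ± 1.13 held-out transcripts per cell against 0.0557 ± 0.0501 (SD, n = 4), and Calb2 was 76.7-fold and Calb1 11.5-fold higher. The serotonin receptor gene Htr2c was 35.2-fold higher in its cluster, the cerebellin gene Cbln4 44.0-fold and the transcription factor Bhlhe22 43.6-fold. Car4 was 30.6-fold higher in the Myo5c cluster (log2 difference 4.94 ± 0.23, SE, edgeR adjusted p = 1.63e-09), followed by Nrp2 at 15.7-fold, the ephrin receptor gene Epha8 at 10.1-fold, Cbln1 at 9.23-fold and Sox5 at 8.69-fold. The count was 71 genes higher in the Myo5c cluster and 83 in the Htr2c cluster, and 149 of the 154 also passed in the same direction with clusters formed without them. Calcium-binding proteins split 1 and 4 between the Myo5c and Htr2c clusters among 7 tested (5 adjusted over the list alone). Axon guidance and adhesion genes split 7 and 7 among 19 (14 adjusted over the list alone), and transcription factors 3 and 5 among 19 (8), with Foxp2 19.2-fold higher in the Htr2c cluster. Channel and receptor genes split 3 and 5 among 12 (9 adjusted over the list alone). Neuropeptide and receptor genes split 1 and 4 among 8 (5 adjusted over the list alone). Release-machinery genes split 1 and 3 among 10 (4 adjusted over the list alone), with Rab3b 42.4-fold higher in the Htr2c cluster. Transmitter genes split 1 and 1 among 4 (2 adjusted over the list alone). Slc17a6 was 1.43-fold higher in the Myo5c cluster (edgeR adjusted p = 0.0139), a call that ended without replicate 1 (0.114) or replicate 2 (0.0786), and Gad2 was 4.53-fold higher in the Htr2c cluster. Activity-regulated genes split 1 and 1 among 5 (2 adjusted over the list alone), matrix genes 1 and 1 among 8 (2), and glial, vascular and meningeal markers 2 and 4 among 47 (4).

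The Pamr1 and C1ql2 clusters differed with Calb1, Necab1 and Ramp3 on one side and Slit2, Sncg and Slc17a7 on the other. Calb1 was 110-fold higher in the Pamr1 cluster, at 4.08 ± 2.44 held-out transcripts per cell against 0.0440 ± 0.0106 (SD, n = 4), Ramp3 99.4-fold and Necab1 38.1-fold. C1ql2, which encodes a secreted synaptic organiser, was 158-fold higher in the cluster named for it, Slit2 66.5-fold, Sncg 13.8-fold and Slc17a7 10.7-fold. For Slit2 the log2 difference was -6.06 ± 0.68 (SE, edgeR adjusted p = 4.10e-06). A total of 74 genes were higher in the Pamr1 cluster and 73 in the C1ql2 cluster (50.3% higher in the Pamr1 cluster, against 41.3% of 155 genes with library-size scaling), and 133 of the 147 also passed in the same direction with clusters formed without them. Calcium-binding proteins split 3 and 3 between the Pamr1 and C1ql2 clusters among 7 tested (6 adjusted over the list alone), with Cabp7 13.0-fold higher in the C1ql2 cluster. Axon guidance and adhesion genes split 3 and 10 among 19 (14 adjusted over the list alone). Transcription factors split 6 and 4 among 19 (10 adjusted over the list alone), with Foxp2 19.5-fold higher in the Pamr1 cluster and Bhlhe22 14.5-fold higher in the C1ql2 cluster. Channel and receptor genes split 4 and 3 among 12 (7 adjusted over the list alone), neuropeptide and receptor genes 3 and 1 among 8 (4), and release-machinery genes 3 and 2 among 10 (5). Matrix genes split 1 and 4 among 8 (5 adjusted over the list alone), with the bone matrix gene Spp1 41.9-fold higher in the Pamr1 cluster. Activity-regulated genes split 1 and 2 among 5 (3 adjusted over the list alone), and Slc17a7 was the 1 transmitter gene of 4 that passed (1). Of 47 glial, vascular and meningeal markers, 2 were higher in the Pamr1 cluster and 9 in the C1ql2 cluster (10 adjusted over the list alone).

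The Pamr1 and Htr2c clusters were told apart by the transcription factor Bhlhe22, by Htr2c and by 2 cerebellins, while Calb1 and Necab1 did not pass the test (log2 difference 0.18 ± 0.41 and -1.65 ± 0.64, SE). Bhlhe22 was 39.8-fold higher in the Htr2c cluster (log2 difference -5.31 ± 0.35, SE, n = 4, edgeR adjusted p = 1.60e-07), Htr2c 12.2-fold, Cbln4 10.4-fold and Calb2 6.02-fold. Cbln1, a cerebellin that organises synapses, was 10.7-fold higher in the Pamr1 cluster, the opsin gene Opn3 6.38-fold and Epha8 4.81-fold. In total, 53 genes were higher in the Pamr1 cluster and 48 in the Htr2c cluster (52.5% higher in the Pamr1 cluster, against 43.5% of 108 genes with library-size scaling and 46.2% of 117 with DESeq2), and 93 of the 101 also passed in the same direction with clusters formed without them. Calb2 was the 1 calcium-binding protein of 7 that passed (1 adjusted over the list alone). Axon guidance and adhesion genes split 4 and 6 between the Pamr1 and Htr2c clusters among 19 tested (10 adjusted over the list alone), with Sema5b 7.04-fold higher in the Htr2c cluster, a call that ended without replicate 1 (edgeR adjusted p = 0.0577). Channel and receptor genes split 2 and 5 among 12 (7 adjusted over the list alone), transcription factors 4 and 2 among 19 (6), and neuropeptide and receptor genes 2 and 2 among 8 (4). Release-machinery genes split 2 and 3 among 10 (5 adjusted over the list alone), and 1 activity-regulated gene of 5 (1) and 1 transmitter gene of 4 (1) passed. No matrix gene of 8 passed with edgeR, over all genes or adjusted over the list alone. All 5 of 47 glial, vascular and meningeal markers that passed were higher in the Htr2c cluster (2 adjusted over the list alone). The count of genes was 64 without replicate 1 and 57 without replicate 2.

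Between the C1ql2 and Htr2c clusters, C1ql2, Sncg, Rspo3 and Slc17a7 marked one side and Necab1, Calb1 and Foxp2 the other. C1ql2 was 178-fold higher in its cluster, Sncg 20.7-fold, the Wnt-pathway ligand gene Rspo3 18.8-fold and Slc17a7 18.2-fold. Necab1 was 120-fold higher in the Htr2c cluster, Calb1 96.7-fold and Htr2c 44.6-fold. For the forkhead transcription factor Foxp2, also higher in the Htr2c cluster, the log2 difference was -5.75 ± 0.40 (SE, n = 4, edgeR adjusted p = 1.04e-07). The split was 79 genes higher in the C1ql2 cluster and 75 in the Htr2c cluster (51.3% higher in the C1ql2 cluster, against 47.3% of 165 genes with DESeq2), and 135 of the 154 also passed in the same direction with clusters formed without them. Axon guidance and adhesion genes split 9 and 6 between the C1ql2 and Htr2c clusters among 19 tested (15 adjusted over the list alone), with Slit2 9.30-fold higher in the C1ql2 cluster. Transcription factors split 6 and 7 among 19 (13 adjusted over the list alone), calcium-binding proteins 2 and 4 among 7 (6), and neuropeptide and receptor genes 1 and 4 among 8 (5). All 5 activity-regulated genes passed (5 adjusted over the list alone), and 3 of them also passed with clusters formed without them. Of these, 4 were higher in the C1ql2 cluster, while Fos was 4.92-fold higher in the Htr2c cluster. Bdnf, at 2.32-fold, and Arc, at 2.23-fold, were both higher in the C1ql2 cluster, and neither passed with clusters rebuilt on the other part of the counts (edgeR adjusted p = 0.0785 and 0.121). Arc also no longer passed without replicate 1 (0.0687) or replicate 4 (0.0513). Release-machinery genes split 2 and 3 among 10 (5 adjusted over the list alone), channel and receptor genes 2 and 3 among 12 (5), transmitter genes 1 and 1 among 4 (2), and matrix genes 2 and 1 among 8 (2). Of 47 glial, vascular and meningeal markers, 8 were higher in the C1ql2 cluster and 1 in the Htr2c cluster (8 adjusted over the list alone), and the astrocyte gene Gfap was 9.27-fold higher in the C1ql2 cluster.

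The next question was how expression in candidate thalamic neurons changed along the anterior to posterior axis, with all 7 sections in one fit that had no term for the replicate number, a choice on which the counts of position genes depend. With counts summed over all 7 neuron clusters, no gene of 295 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test between posterior and anterior sections (10 genes at an unadjusted p under 0.05). None passed between intermediate and anterior sections (0 unadjusted) or between posterior and intermediate sections (5 unadjusted), and DESeq2 also called 0 in each. Sections of one replicate number deviated together (correlation 0.868 over 295 genes, anterior against intermediate sections), and this fit counts that as error. The correlation cannot part a shared deviation within cells from a shared mix of clusters. For example, the Tacr1 cluster held 0.11% and 0.226% of neurons in anterior and intermediate replicate 1, against 24.4% and 16.8% in replicate 2. A replicate block changed these calls, but it takes the posterior difference from replicate 1 alone. The counts of 0 therefore do not show that position had no effect. The parvalbumin gene Pvalb had a posterior minus anterior log2 difference of 2.45 ± 0.81 (SE, 3 against 2 sections), Slc17a7 of 1.72 ± 1.08 and Rab37 of 1.39 ± 1.04, all with an adjusted p of 0.942. Posterior replicate 3 lay below the other posterior sections for these genes, with log2 CPM of 9.63 for Pvalb against 11.79 and 12.57 in posterior replicates 1 and 4. This section was singled out after the results were seen, and every position test without it rests on 2 sections per position and 3 residual degrees of freedom. Without it 3 genes passed edgeR's test, namely Pvalb (2.91 ± 0.33, adjusted p = 0.0352), Slc17a7 (2.26 ± 0.28, adjusted p = 0.0352) and Rab37 (1.93 ± 0.26, adjusted p = 0.0369). Adjusted over the list alone, 1 of 15 neuropeptide and receptor genes passed with edgeR between posterior and anterior sections and 1 between posterior and intermediate sections. In the fit without posterior replicate 3 none of that list passed between posterior and anterior sections, while 4 of 10 release-machinery genes, 2 of 7 calcium-binding proteins, 2 of 12 channel and receptor genes, 2 of 5 transmitter genes and 1 of 20 guidance genes did. These sums mix clusters whose shares differed between sections, so each cluster was also tested alone.

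Within the C1ql2 cluster, Pvalb had a posterior minus anterior difference of 4.03 ± 0.74 on the log2 scale (SE, 3 against 2 sections), the guidance gene Sema5b by 3.78 ± 0.83, the synaptotagmin gene Syt2 by 2.92 ± 0.62 and Cabp7 by 2.31 ± 0.54. Unc13c, a synaptic vesicle priming factor, differed by -1.72 ± 0.35 and Necab2 by -1.80 ± 0.48. With edgeR no gene of 227 passed (37 unadjusted, lowest adjusted p = 0.0838), whereas DESeq2 called 5, which were Pvalb, Sema5b, Syt2, Cabp7 and Unc13c. Adjusted over the list alone, 3 of 6 calcium-binding proteins, 4 of 10 release-machinery genes, 1 of 18 guidance genes and 1 of 9 channel genes passed with edgeR. Posterior replicate 3 had 17 cells in this cluster, and without it (2 against 2 sections) 68 genes passed, 31 higher and 37 lower in posterior sections. Those included Pvalb (4.24 ± 0.35), Syt2 (3.04 ± 0.30), Cbln1 (-3.16 ± 0.33), Rab3b (-2.21 ± 0.35), Calb2 (-1.53 ± 0.10), Slc17a7 (0.94 ± 0.11) and Fos (1.83 ± 0.41). Rab3b was at -0.997 with all sections and turned to 0.42 without posterior replicate 1, 0.61 without posterior replicate 4 and 0.42 with DESeq2. Endothelial-like cells of the candidate clusters, a cell type not known to make Pvalb, also had more of it in posterior replicates 1 and 4 than in anterior sections (log2 ratio 1.90). The Pvalb values may therefore include transcripts of other cells. Those endothelial-like cells lay in clusters picked for high Slc17a6, and endothelial clusters outside the candidates were not examined for Pvalb. In that fit 1 release-machinery gene of 10 was higher and 7 were lower in posterior sections (8 adjusted over the list alone), 4 channel genes of 11 were higher (4) and 3 activity-regulated genes of 5 were higher (4). Calcium-binding proteins split 2 and 2 among 6 (4 adjusted over the list alone), guidance genes 1 and 4 among 18 (5), neuropeptide and receptor genes 1 and 1 among 6 (2) and transcription factors 1 and 1 among 18 (2). Of 35 glial, vascular and meningeal markers 3 passed in it (0 with edgeR adjusted over the list alone). With the slide as a term, Cabp7 alone passed edgeR's test among all 7 sections (2.94, adjusted p = 0.0453), and since 1 slide held only posterior sections no value within that slide could be had. The genes named by position, and Calb1 and Necab1 between the Pamr1 and Htr2c clusters, fell outside the rule set for named genes and were chosen after their values were seen.

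**Figure D2:**
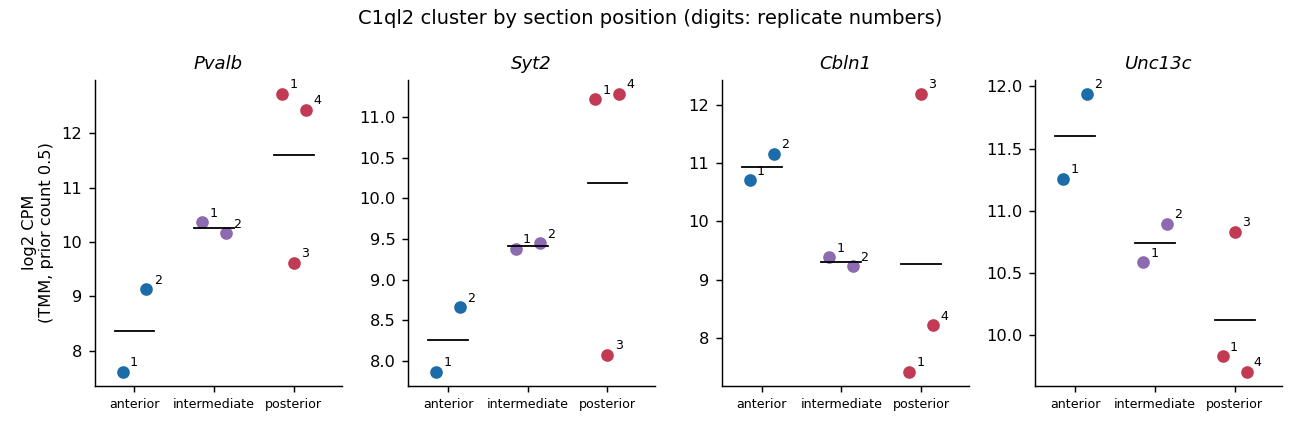
Log2 CPM, counts scaled to a common library size (TMM-scaled, prior count 0.5, vertical axes not starting at 0) of Pvalb, Syt2, Cbln1 and Unc13c in the C1ql2 cluster, 1 point per section with its replicate number, by position (horizontal axis), and lines at the group means. Posterior replicate 3 lies apart from posterior replicates 1 and 4 in each panel, for example at 9.62 against 12.73 and 12.44 for Pvalb.

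Within the Myo5c cluster Pvalb, the insulin-like growth factor gene Igf1, Rab37 and the ephrin receptor gene Epha4 had positive posterior minus anterior differences. With all sections these were 1.81 ± 0.48, 1.91 ± 0.83, 1.25 ± 0.88 and 0.99 ± 0.67 on the log2 scale (SE, 3 against 2 sections). No gene of 241 passed with edgeR (11 unadjusted) or DESeq2. Without posterior replicate 3 (2 against 2 sections, 3 residual degrees of freedom), 80 genes passed edgeR's test, 39 higher and 41 lower in posterior sections, among them Rab37 (1.79 ± 0.12), Pvalb (2.17 ± 0.19), Epha4 (1.47 ± 0.13), Igf1 (2.43 ± 0.39), Adarb2 (1.35 ± 0.18) and, lower in posterior sections, Calb1 (-1.18 ± 0.24) and C1ql2 (-2.09 ± 0.47). In that fit 1 calcium-binding protein was higher and 3 were lower among 7 tested (4 adjusted over the list alone), transcription factors split 4 and 4 among 17 (8), guidance genes 3 and 5 among 17 (9), neuropeptide and receptor genes 2 and 2 among 6 (4), activity-regulated genes 3 and 1 among 5 (4) and release-machinery genes 1 and 2 among 9 (3), and 4 of 48 glial, vascular and meningeal markers passed (1). Channel and receptor genes split 3 and 0 among 11 (3 adjusted over the list alone) and matrix genes 0 and 1 among 8 (1). Rab37, Pvalb, Epha4 and Adarb2 are also among the 10 leading genes of the Pvalb cluster. That cluster held 12.7% and 27.0% of neurons in posterior replicates 1 and 4 and at most 0.11% in anterior sections. Cells of that cluster placed in the Myo5c cluster would bring its other abundant transcripts as well. In posterior replicates 1 and 4, 9 such genes stood at a median of 0.2755 (0.0144 to 0.623) of the level that the Pvalb rise would need. This argues against misplaced cells with that cluster's average levels as the full source of the Pvalb rise. Whether fewer such cells add to it, or to the values of Rab37, Epha4 and Adarb2, was not tested. Pvalb also varied by section in endothelial-like cells of the candidate clusters, at 708 and 959 CPM in anterior replicates 1 and 2, 561 and 879 CPM in intermediate replicates 1 and 2, 2137 and 4087 CPM in posterior replicates 1 and 4, and 207 CPM, from 3 transcripts, in posterior replicate 3.

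In the Htr2c cluster Rxfp1, a relaxin-family receptor gene, had the largest positive difference among the genes named (2.63 ± 1.06 on the log2 scale, SE, 3 against 2 sections), and Zfpm2 (-2.13 ± 0.60) and Cbln1 (-1.86 ± 0.52) had negative ones. No gene of 253 passed with edgeR (9 unadjusted) or DESeq2 in this cluster. Without posterior replicate 3 (2 against 2 sections), 31 genes passed, 13 higher and 18 lower in posterior sections, including Rxfp1 (2.96 ± 0.61), Epha4 (1.03 ± 0.18), Rab3b (-2.83 ± 0.27), Zfpm2 (-2.79 ± 0.58), Cbln1 (-1.50 ± 0.37) and the opioid precursor gene Penk (-2.28 ± 0.63). Adjusted over the list alone, 2 of 9 genes of the neuropeptide and receptor list passed with all sections and 7 of 8 without posterior replicate 3. The 7 included Cbln1, Igf1 and Bdnf, which are neither neuropeptides nor their receptors. Without posterior replicate 3, 3 of 4 transmitter genes, 2 of 11 channel genes, 2 of 17 transcription factors, 1 of 18 guidance genes and 1 of 10 release-machinery genes also passed. Of 43 glial, vascular and meningeal markers 2 passed without posterior replicate 3, both lower in posterior sections (0 with edgeR adjusted over the list alone). Rxfp1 and Epha4 are also among the 10 leading genes of the Pvalb cluster, and whether misplaced cells of that cluster add to their values was not tested. Gad2 turned from 0.71 ± 1.13 with all sections to -1.49 ± 0.47 without posterior replicate 3. Rab3b was at -0.26 with all sections and turned to 0.04 without anterior replicate 1, 0.36 without posterior replicate 1 and 0.38 without posterior replicate 4. In the Pamr1 cluster no gene of 264 passed with edgeR (5 unadjusted) or DESeq2, and 0 of 259 passed with edgeR without posterior replicate 3 (41 unadjusted). Of its neuropeptide and receptor genes, 1 of 9 passed with all sections adjusted over the list alone, and without posterior replicate 3 1 of 8 did, with 1 of 7 calcium-binding proteins, 2 of 19 guidance genes and 1 of 4 transmitter genes. Whether the position difference itself differed between the 4 clusters was tested as an interaction of cluster and position. No gene of 258 passed with edgeR (13 unadjusted), where Unc13c had the lowest adjusted p (0.121). DESeq2 called 2, Pvalb and Unc13c, and edgeR called 52 without posterior replicate 3.

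The last comparison was the share of each cluster among candidate neurons per section. The Pamr1 cluster made up 26.8% ± 0.288 of neurons in anterior sections (SD, n = 2) and 14.6% ± 8.28 in posterior sections (SD, n = 3), and the Myo5c cluster 35.9% ± 21.8 and 29.7% ± 12.9. Htr2c-cluster cells made up 16.5% ± 11.8 and 24.5% ± 19.6, and C1ql2-cluster cells 8.29% ± 7.32 and 13.2% ± 9.47. The Pvalb cluster held 12.7% of neurons in posterior replicate 1 (95% Wilson interval 11.1 to 14.5) and 27.0% in posterior replicate 4 (24.8 to 29.2), but 0 of 757 in posterior replicate 3, which allows a share of up to 0.396%. It held 4.53% in intermediate replicate 2 and at most 0.602% in the other sections. The Tmem132d cluster held 5.71% and 6.16% in posterior replicates 1 and 4 and 0 of 757 in posterior replicate 3. The Tacr1 cluster held 24.4% in anterior replicate 2 and 16.8% in intermediate replicate 2, against at most 1.45% in the other sections. In posterior replicate 3 the Myo5c and Htr2c clusters held 43.3% and 47.0% of 757 neurons, the Pamr1 cluster 5.95% and the C1ql2 cluster 2.25%. No share differed between posterior and anterior sections in a two-sided exact permutation test (p from 0.2 to 0.8 over 7 clusters, Benjamini-Hochberg adjusted p from 0.7 to 0.8). With 2 against 3 sections the smallest p this test allows is 0.1. The sign of the difference turned for the Myo5c cluster without anterior replicate 1 (from -6.17 to 9.25 percentage points), for the C1ql2 cluster without anterior replicate 2 (from 4.89 to -0.285) and for the Tacr1 cluster without anterior replicate 2 (from -11.4 to 0.759). For the Htr2c cluster it turned from 7.95 to -3.33 without posterior replicate 3 and to -0.416 without anterior replicate 1. The difference kept its sign but moved from -12.2 to -7.92 percentage points for the Pamr1 cluster and from 3.82 to 5.80 for the Tmem132d cluster without posterior replicate 3, and for the Pvalb cluster from 13.1 to 19.7 without posterior replicate 3 and to 6.27 without posterior replicate 4. Intervals and limits cover counting error only, and the plane of a hemisection sets how many cells of each cluster it can hold.

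**Figure D3:**
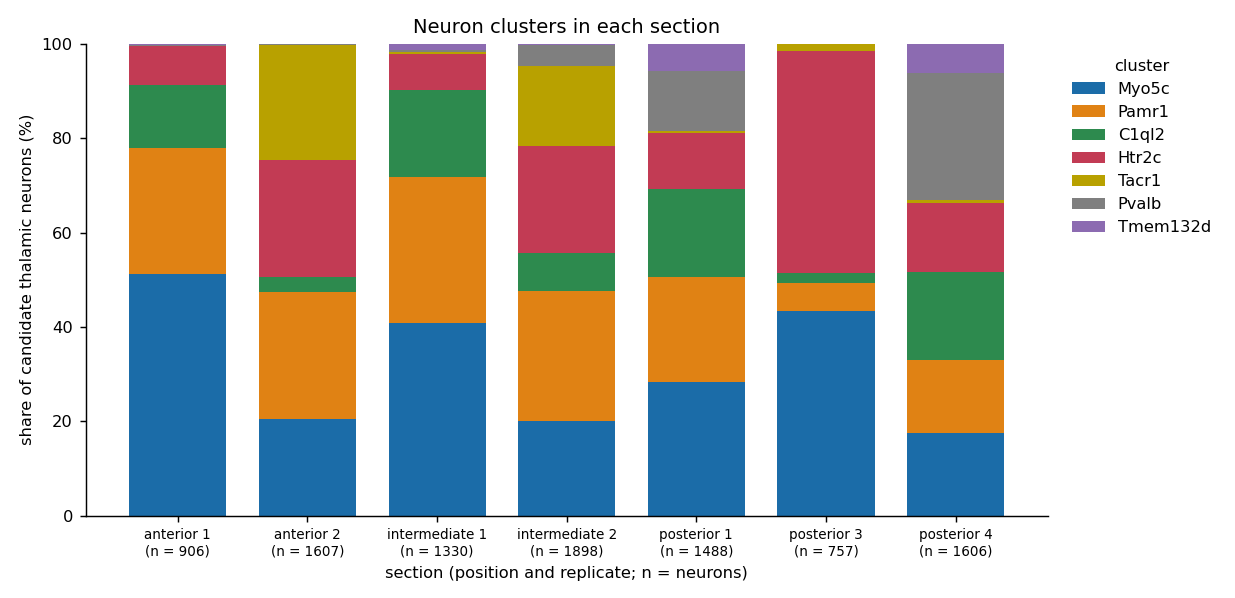
Share of candidate thalamic neurons (vertical axis, percent) in each of the 7 clusters per section (horizontal axis, with the number of neurons n), stacked to the whole. The Tacr1 cluster is wide in anterior replicate 2 (24.4%) and intermediate replicate 2 (16.8%), and the Pvalb cluster in posterior replicate 4 (27.0%).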

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

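The tests of posterior replicate 3, the later tests of the Tacr1 cluster and the counts of other groupings were chosen after the results were seen, as was the test of neighbouring Pvalb-cluster cells, whereas the test of Pvalb in endothelial-like cells and the first test of the Tacr1 cluster were set before theirs.

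Among 84 gene and pair combinations, 9 had a replicate far from the other replicates, and chance alone gives about 1 in 20. Of these, 7 concerned replicate 3, which has 45 Pamr1-cluster and 17 C1ql2-cluster cells. Between the Myo5c and C1ql2 clusters, the log2 difference of Slc17a7 was -2.13 in replicate 3 and -5.32 to -4.86 in the others. Between the Myo5c and Htr2c clusters, Foxp2 stood at -5.19 in replicate 3 against -3.99 to -3.91. Between the Pamr1 and C1ql2 clusters, replicate 3 gave 3.58 for Calb1 (others 6.95 to 7.17) and, from 0 Sncg transcripts in the Pamr1 cluster, -8.27 for Sncg (others -4.41 to -3.65). Between the Pamr1 and Htr2c clusters, Slit2 was 1.67 in replicate 3 against -3.70 to -2.84, and Pdyn was 6.45 in replicate 1, from 0 transcripts in the Htr2c cluster, against 2.65 to 2.71. Between the C1ql2 and Htr2c clusters, replicate 3 gave -12.14 for Htr2c (others -5.73 to -4.58) and -9.25 for Fos (others -2.52 to -1.17), both from 0 transcripts in the C1ql2 cluster, and replicate 2 gave 4.59 for Slc17a7 (others 3.94 to 4.04). Where a count was 0 the size of the value is set by the prior count added before taking logs, and is not a measured difference. Outside the thalamic clusters, hippocampal excitatory-like cells numbered 1652 in posterior replicate 1 (3.15% of cells), 1384 in posterior replicate 3 (2.28%) and 397 in posterior replicate 4 (0.791%), against at most 38 in any anterior or intermediate section.

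Posterior replicate 3 differed from posterior replicates 1 and 4 in its thalamic clusters. Its 1384 hippocampal excitatory-like cells, against at most 38 in anterior and intermediate sections, argue against a section of those levels under the posterior label. Its number of Myo5c-cluster cells was 0.933 of the mean of the other posterior sections while those of the Pamr1 and C1ql2 clusters were 0.155 and 0.0589 of it. Median transcripts per cell were lower there in the Myo5c cluster (417.5 against 593 and 550 in posterior replicates 1 and 4), the Pamr1 cluster (362 against 645 and 663.5) and the C1ql2 cluster (396 against 565 and 500), but not in the Htr2c cluster (553 against 584 and 545). Lower detection can also move cells between clusters, so cell numbers cannot exclude it and it stays open. The section held 0.489 of the mean number of candidate neurons of the other posterior sections, so a plane of section with less of some nuclei may account for the pattern, and without cell positions this stays open. A difference between the brains sectioned also stays open and was not tested.

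Pvalb was higher in the Myo5c cluster of posterior replicates 1 and 4 than in that of the anterior sections. Of 12 genes over 4-fold higher in the Pvalb than in the Myo5c cluster, Pvalb included, 8 were higher there (median log2 difference 0.34). Of these 12, 4 passed edgeR's test, with Pvalb, Adarb2 and Oprm1 higher and Calb1 lower. Of 170 genes within 2-fold, 98 were higher (median 0.07), which leaves open whether the 12 rose as a group. Transcripts of neighbouring Pvalb-cluster cells counted in Myo5c-cluster cells would bring all their abundant transcripts. The other 9 such genes with at least 1 held-out transcript per Pvalb-cluster cell stood at a median of 0.2755 (0.0144 to 0.623 over both sections) of the level that the rise of Pvalb would need, which argues against such cells as the cause. Pvalb was also higher in endothelial-like cells of the candidate clusters, which are not known to make it, with a log2 ratio of 1.90 between the means of posterior replicates 1 and 4 and of the anterior sections. This goes with a spread of Pvalb transcripts into cells that do not make them, and its source was not looked for. Those cells lay in clusters picked for high Slc17a6, and endothelial clusters outside the candidates were not examined, so the value covers these cells alone. A difference of position within Myo5c-cluster neurons stays open beside it.

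The Tacr1 cluster was found almost only in the replicate 2 sections. The median log2 ratio of its leading genes between replicates 2 and 1 in the Myo5c, Pamr1 and Htr2c clusters was 0.71, between the bounds set for and against a rise over all cells of replicate 2, so that stays open. Htr2c-cluster cells placed in another cluster would lower the Htr2c share among neurons outside the Tacr1 cluster. It was at least 27.5% in the anterior and intermediate sections of replicate 2 and at most 8.18% in those of replicate 1, but the shares compare only if both replicates hold the same tissue, so this stays open. Of 32 clusters outside the candidate ones, 4 differed over 2-fold in cell number the same way at both positions, 3 higher and 1 lower in replicate 2, consistent with different tissue in those sections. Of the 3 higher ones, 1 with 12120 cells had Calb2, Slc17a6 and Tacr1 among its leading genes. It met the Slc17a6 rule for candidates (log2 difference 2.95 from all other cells) but not the Gad1 and Gad2 rule. It held 801 and 1061 cells in the anterior and intermediate sections of replicate 1, and 2642 and 2741 in those of replicate 2. The pattern of the Tacr1 cluster thus holds for candidate cells only. No biological explanation was tested, since the labels do not describe the replicates further.

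Other groupings of the 8 sums of each pair into 4 and 4 were refitted for the count of genes. There were 35 groupings for each pair, of which 3 could not be estimated, and 1 of 35, the real one, gave as many genes as the real one in each of the 6 pairs. The real grouping gave 96 genes for the Myo5c and Pamr1 clusters (highest other 1), 163 for Myo5c and C1ql2, 145 for Myo5c and Htr2c, 147 for Pamr1 and C1ql2, 85 for Pamr1 and Htr2c and 142 for C1ql2 and Htr2c (highest other 0 with edgeR in these 5). The clusters were drawn from expression in the same cells, so the real grouping was bound to give many genes, and these splits leave open whether chance could give them.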

How the results depend on the processing

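Clustering on all counts, clustering without the tested genes and sums over the 4 compared clusters alone were chosen after seeing the data. So were, for position, clusters rebuilt on the other part of the counts, and all other alternatives were chosen before. Of 1171 values of the checked gene and cluster pair combinations under the alternatives, 1157 kept their direction and side of the threshold, 14 kept their direction but no longer passed, and 0 reversed. These genes had been picked for passing the main test, so few were likely to move, and the values do not measure how stable the counts of genes are. Of 462 such values by position, 397 kept both, 55 passed only under the alternative and 10 reversed. Between the Myo5c and Pamr1 clusters 127 genes passed with sections as units and a section block, and 57 to 131 with each replicate left out; between the Pamr1 and Htr2c clusters 57 to 134 did. The cause was not tested. Scaling by library size moved the median log2 difference of all genes from 0.11 to -0.14 between the Pamr1 and C1ql2 clusters, from 0.02 to -0.13 between Myo5c and C1ql2 and from 0.04 to -0.13 between Pamr1 and Htr2c, and DESeq2 moved it from 0.03 to -0.12 between C1ql2 and Htr2c and from 0.04 to -0.09 between Pamr1 and Htr2c. With a replicate block (1 residual degree of freedom) 83, 22 and 42 genes passed over all neurons between posterior and anterior, intermediate and anterior, and posterior and intermediate sections, 49, 32, 17 and 24 within the Myo5c, Pamr1, C1ql2 and Htr2c clusters, and 47 in the interaction. The replicate difference, in sums over all neurons, correlated over 295 genes between anterior and intermediate sections (0.868). Sections of one number thus deviated together, whether within their cells or in their mix of clusters. The fit without a block counts this shared difference as error. The fit with it takes the posterior difference from replicate 1 alone, so neither set of counts settles the effect of position. The labels do not say what a shared number stands for. DESeq2 called 5 genes within the C1ql2 cluster and 2 in the interaction, and edgeR with the slide as a term called 1 within the C1ql2 cluster. With each section left out, the counts ran from 0 to 3 over all neurons, 0 to 80 within Myo5c, 0 to 68 within C1ql2, 0 to 31 within Htr2c and 0 to 52 in the interaction, the highest always without posterior replicate 3. Shares (posterior minus anterior, percentage points) ran from -21.6 to 9.25 for Myo5c, -0.285 to 10.4 for C1ql2, -3.33 to 16.3 for Htr2c and -23.5 to 0.759 for Tacr1. By position, Rab3b in the C1ql2 cluster was 0.42 with DESeq2 and -2.21 to 0.61 with sections left out, Meis2 in Myo5c -1.01 to 0.0029, Rab3b in Htr2c -2.83 to 0.38, and Gad2 in Htr2c -1.75 with a replicate block, -1.61 with a slide term and -1.49 to 1.33 with sections left out. The alternatives for anterior against other thalamic neurons were not run because the markers did not separate these classes. Among the 4 compared clusters, the sum of the C1ql2 cluster in posterior replicate 3, with 17 cells, was the shallowest.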

Other observations

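The values that follow describe the smaller clusters, which entered the tests of shares but no pairwise test, with values of compared clusters beside them. Expression in the smaller clusters was not tested against the others, and genes that lead a cluster are not results of a comparison.

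The 3 smaller neuron clusters had these levels. Cells of the Pvalb cluster averaged 7.44 Pvalb transcripts per cell over all counts, against 1.95 in the C1ql2 cluster and 0.861 in the Myo5c cluster, together with 19.9 of the ephrin receptor gene Epha4, 9.52 of Adarb2, 9.38 of Calb1 and 7.29 of Slc17a7, but 0.308 of Calb2. Cells of the Tmem132d cluster averaged 34.2 Calb2 transcripts with 11.9 of Epha4, 9.84 of Ramp3 and 5.67 of Slc17a7. Cells of the Tacr1 cluster, called by the substance P receptor gene (0.578 transcripts per cell), averaged 31.0 of Calb2, 24.3 of Necab1 and 9.49 of Calb1, with 2.88 of Cbln4 and 14.4 of Slc17a6. Cells of the larger Htr2c cluster averaged 25.6 of Calb2, 23.9 of Necab1, 6.42 of Calb1, 1.02 of Cbln4 and 19.6 of Slc17a6.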
